A study of Mus musculus with 6 samples.

How the data were processed

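RNA was measured by sequencing in 6 samples of SCC7, a mouse squamous cell carcinoma line used as a model of head and neck cancer. The labels name 3 untreated control samples and 3 samples that received radiotherapy, with a dose of 9 Gy in the treatment protocol. All 6 samples carry the time label day 0, so the interval between irradiation and harvest is not stated. Per the labels' protocols, total RNA was treated with DNase I and ribosomal RNA was removed before fragmentation and cDNA synthesis. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

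The deposited values are FPKM (fragments scaled by the length of the transcript and by the total of the library), per the file headers, in a table of 17030 genes with NCBI gene identifiers and symbols, rounded to 2 decimals. The submitters' processing notes name HISAT and the mouse genome build GRCm38.p6. The counting tool, the annotation and any filter are not given in the sources used here. The sum of FPKM per library was 693961 to 982553 in the controls and 652691 to 663489 in the irradiated samples. FPKM does not hold the number of reads, and after rounding the steps of the low values could not be resolved into whole reads, so the depth of each library is unknown and no interval that needs it is given. No pair of libraries held identical values. All 6 columns of values were used. FPKM depends on the transcript length that the authors assigned and on the total of each library, so a few abundant genes can shift the scale of all others, and reads from near-identical genes can be assigned to either copy.

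Gene identifiers were matched to the RefSeq annotation of the same build, which held 16976 of them (99.7%), and coordinates are 1-based positions from that annotation. Transcript length and GC content came from GENCODE transcripts of release M21, the same build, and were known for 16613 genes. Genes with at least 1 FPKM in at least 3 samples were kept, which left 11103. These were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, by a linear model with 2 groups and no other term, with eBayes using its trend and robust options and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05, and at 2-fold where its log2 fold change was also at least 1 in size. Fold changes are irradiated minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. Because the unit is FPKM and not counts, no count model was used.

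Gene lists for 27 pathways, complexes and cell types were fixed with the test. Lists with at least 3 genes tested were compared with all other genes by camera of limma, with a preset correlation of 0.01 between genes and adjustment over the 24 lists tested. As an alternative, camera was run with the correlation estimated for each list. Calls within a list are given over all genes tested and adjusted over the list alone. The genes named in the text follow a rule in 3 parts. The first part takes the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap, with a mean of at least 5 FPKM and a symbol that is not a predicted or clone name. The second part takes Cd47, Slc1a5, Gpx4, Slc7a11, Acsl4, Cdkn1a, Mdm2 and Trp53 whatever their values, and a further gene whose result is not reported here. The third part takes the 2 members with the smallest p of each list that passes camera, and the 3 with the smallest p of the ferroptosis defence, ferroptosis driver, glutamine, innate checkpoint and p53 target lists. Further list members appear as examples and were chosen after their values were seen. The groups, the tests, the lists, the rule for named genes and the alternative settings listed next were fixed before the data were examined.

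The procedure was tested on simulated data in which genes varied independently of one another. Each gene had its real SD pooled over both groups, so the unequal spread of the groups was not simulated. Of 100 genes changed 2-fold, 49% were recovered, and of 100 changed 4-fold, 87%, with 9 unchanged genes called among the 10951 tested. Camera found the list that had been shifted and called 0 of the unchanged lists. Because the simulated genes were independent, this does not show how camera treats lists whose genes move together. The alternative settings chosen then were quantile normalization, scaling by a trimmed mean of log ratios, no filter, a filter at 5 FPKM, limma without trend and robust options, a pseudocount of 0.1, the sample number as a block, and the omission of each sample in turn. A correction of each library's trend with transcript length and GC content (splines with 4 degrees of freedom) and a comparison with control 3 as the only control were added after seeing the data. That comparison takes its spread from the irradiated samples, which varied less than the controls. Near-identical copies were searched for with BLAST 2.17.0, as transcripts with at least 95% identity over at least 80% of the query. Genes of a list can move together within a library, so intervals of list medians are 95% Welch intervals whose width comes from the list medians of the 6 libraries, each the median over the list of a gene's value minus its mean. Bootstrap intervals from 10000 draws of the members are named as such.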

Results

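Gene expression was measured in SCC7 cells, a mouse squamous cell carcinoma line, that were left untreated (control, n = 3) or had received radiotherapy at 9 Gy (irradiated, n = 3). Values are FPKM for 17030 genes, and the number of reads behind each library is unknown. The 3 irradiated libraries resembled one another more closely than the 3 controls did. The median SD of a gene on the log2(FPKM + 1) scale was 0.08 among irradiated libraries and 0.30 among controls. Across genes, Pearson correlations were 0.994 to 0.995 between irradiated libraries, 0.989 between controls 1 and 2, 0.956 between controls 1 and 3 and 0.928 between controls 2 and 3. The first principal component held 78.3% of the variance, with controls 1 and 2 at -43.75 and -64.08, control 3 at 8.27 and the irradiated libraries between 29.92 and 35.21. The 20 most abundant genes took 18.2%, 20.9% and 15.1% of the FPKM sum in controls 1 to 3, against 14.3% to 14.4% in the irradiated libraries.

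The comparison of irradiated with control cells asks which transcripts differ after radiotherapy, in a study whose title concerns glutamine inhibition, blockade of the surface protein CD47 and ferroptosis induced by radiotherapy. Irradiated cells showed much higher levels of interferon-stimulated genes, with Usp18, Rtp4, Oasl2, Zbp1 and Irf7 each up by more than 5 on the log2 scale. The p53 target Mdm2 and the chemokines Ccl5 and Ccl2 also rose. Enzymes of cholesterol synthesis fell, among them Fdps, Fdft1, Msmo1 and Mvd, and so did a group of ribosomal protein genes. The ribosomal fall was smaller against control 3 alone (list median -0.26, against -0.72 with all controls), and differences among the libraries stay open as its whole cause. Cd47 rose from 45.2 ± 0.355 to 64.8 ± 1.40 FPKM (SD, n = 3 each, limma adjusted p = 0.0343). That call was lost after trimmed-mean scaling, with the sample number as a block, and without control 1, control 2 or any irradiated library. Gpx4, Slc7a11, Slc1a5, Acsl4 and Trp53 did not pass the test. Gpx4 missed it narrowly, at a larger change than that of Cd47 (log2 fold change -0.72, limma adjusted p = 0.0574). Of 11103 genes tested with limma, 1334 were called, 1026 higher and 308 lower in irradiated cells, and 545 of them differed at least 2-fold (444 higher, 101 lower). The groups did not overlap for 5045 genes (45.4%). A single gene would do so by chance in 10% of cases, but genes move together within a library. The share was not computed for other splits of the libraries, so it does not exclude chance. The split between higher and lower calls depended on the scaling, with 645 higher and 601 lower after quantile normalization and 669 higher and 477 lower after scaling by a trimmed mean of log ratios, since these move the median log2 fold change of all genes from 0.17 to -0.02 and -0.01. The number of calls also changed with the libraries included. It was 180, 548 and 7638 without control 1, 2 or 3 and 56, 65 and 99 without irradiated library 1, 2 or 3. Without control 3, the calls were 7638 of 11053 genes tested (5067 higher, 2571 lower), and list counts in that setting are to be read against this share. Leaving out an irradiated library left fewer samples but hardly moved the log2 fold changes of Cd47 (0.49 to 0.52) and Cdkn1a (0.87 to 0.91). A call lost there therefore need not mean that the change rested on that library. In comparisons with control 3 alone, the spread comes from the irradiated libraries, which varied less than the controls did, so the p-values and calls of those comparisons serve as a description. The main fit, too, assumes the same variance in both groups, although the median SD was 0.30 among controls and 0.08 among irradiated libraries. Its p-values are therefore approximate.

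**Figure D1:**
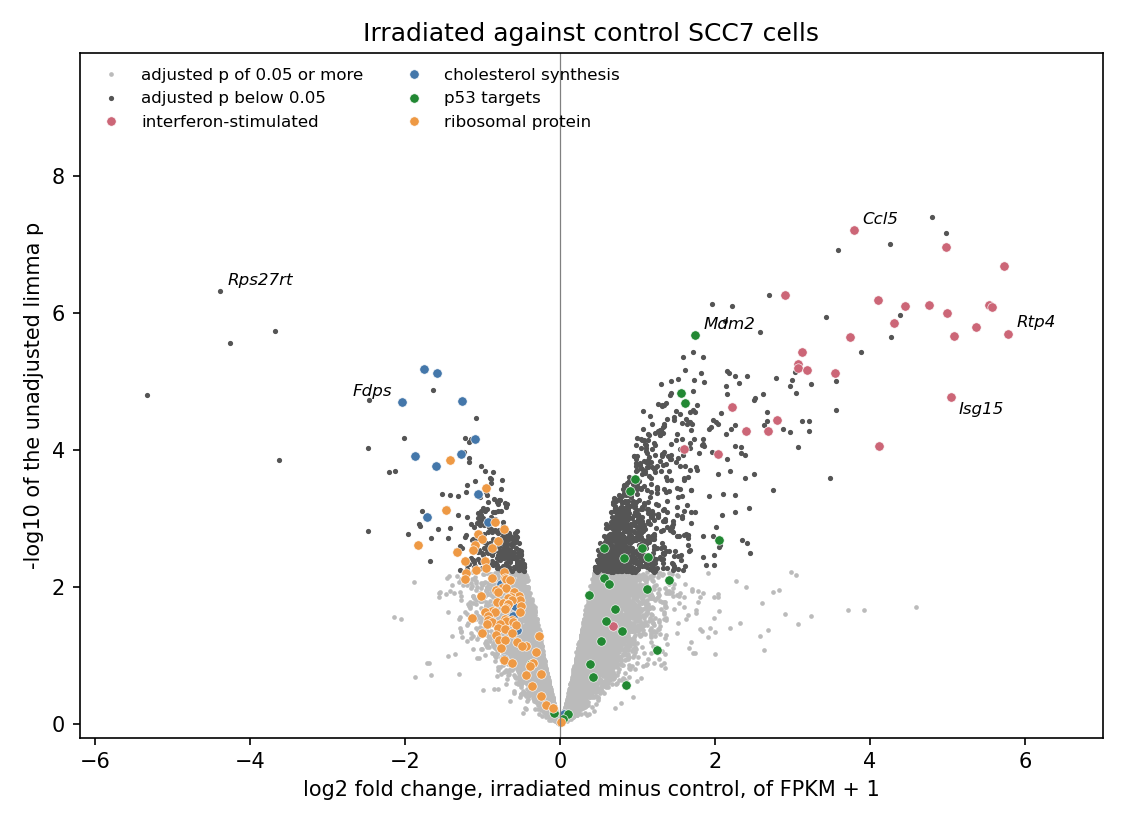
Each point is 1 of 11103 genes, with the log2 fold change of FPKM + 1 (irradiated minus control, n = 3 each) on the x axis and -log10 of the unadjusted limma p on the y axis. Coloured points are members of 4 fixed lists: interferon-stimulated genes lie at the far right, and cholesterol synthesis and ribosomal protein genes lie mostly to the left of 0.

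Interferon-stimulated genes formed the group with the greatest rise among the lists tested. Of 29 members tested, 28 rose, and 29 when adjusted over the list alone. Their median log2 fold change was 3.79, against 0.17 for all genes. Isg15, a ubiquitin-like modifier (NCBI gene 100038882, chromosome 4, 156199424 to 156200818), rose from 13.4 ± 10.2 to 415 ± 118 FPKM, a log2 fold change of 5.04 (SE 0.47, limma adjusted p = 0.00263). Rtp4 (NCBI gene 67775, chromosome 16, 23520219 to 23614222) rose from 1.44 to 122 FPKM and had a log2 fold change of 5.79 (SE 0.39, adjusted p = 0.000838). Usp18, which removes ISG15 from proteins, rose by 5.73, the antiviral sensors Zbp1 and Oasl2 by 5.53 and 5.58, and the transcription factor Irf7 by 5.36. Ifit1 and Ifi44 rose by 5.08 and 4.99, and Oas2, an enzyme that activates RNase L, by 4.99. Ccl5, a T cell chemoattractant, rose from 15.8 ± 2.67 to 229 ± 11.8 FPKM (log2 fold change 3.79, SE 0.15). Ifit2 was the member that missed the threshold over all genes, with a log2 fold change of 0.69 (adjusted p = 0.111). The list passed camera (adjusted p = 1.97e-24) but not with an estimated correlation (adjusted p = 0.386 with an estimated correlation). Without irradiated library 1, 2 or 3, the members called were 15, 16 and 19, of only 20 that then passed the filter.

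**Figure D2:**
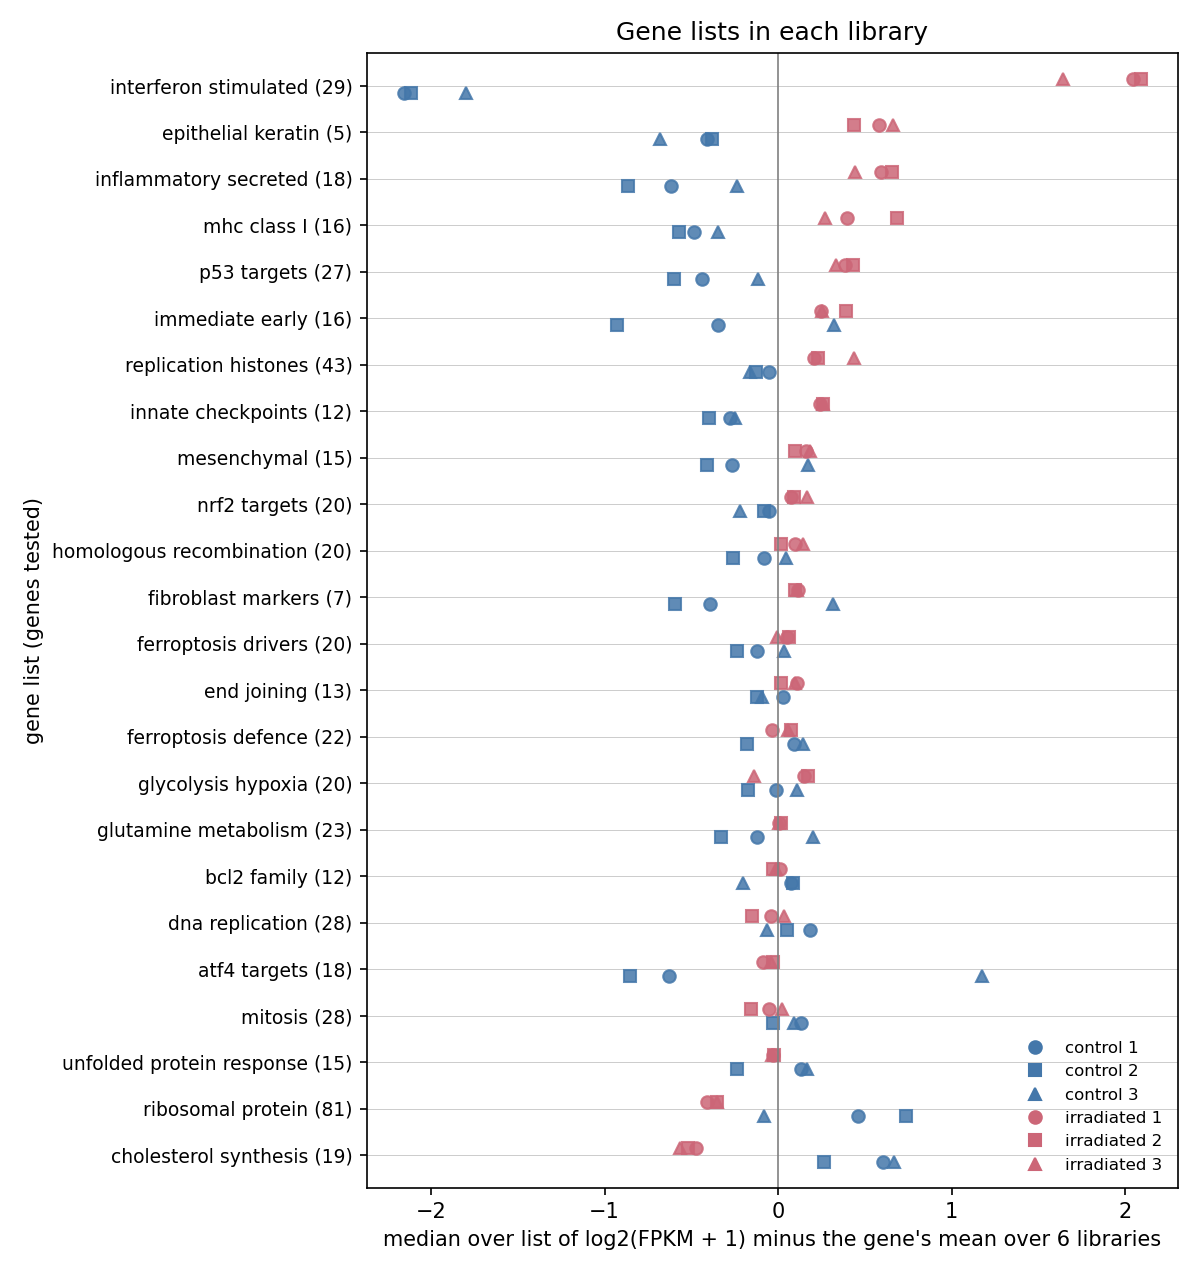
Each row is a fixed gene list with the number of genes tested, and each point is 1 library: the x axis gives the median over the list of log2(FPKM + 1) minus each gene's mean over the 6 libraries. Interferon-stimulated genes separate the irradiated from the control libraries widely, whereas ATF4 target genes are highest in control 3 and ribosomal protein genes are lowest among controls in control 3.

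Most tested genes of MHC class I antigen presentation were also called higher in irradiated cells. Of 16 tested, 11 rose, and 12 when adjusted over the list alone, with a median of 0.88 (camera adjusted p = 1.79e-05, adjusted p = 0.471 with an estimated correlation). The peptide transporter Tap1 rose from 11.6 ± 0.257 to 26.4 ± 3.39 FPKM (log2 fold change 1.11, SE 0.14, adjusted p = 0.00586) and its partner Tapbp from 58.2 to 136 FPKM. B2m, the invariant light chain of class I molecules, rose from 1506 to 4504 FPKM. Tap1 lost its call without irradiated library 1 or 2 (adjusted p = 0.0783 and 0.0761), and Tapbp without control 1 (0.0663) or irradiated library 1, 2 or 3 (0.103, 0.106 and 0.0567). After trimmed-mean scaling 7 members rose. The count of risen members was 1, 7 and 13 without control 1, 2 or 3 and 0, 0 and 1 without irradiated library 1, 2 or 3, where at an unadjusted p below 0.05 the full comparison had 12.

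Secreted inflammatory factors and NF-kB targets rose in 9 of 18 genes tested, and in 10 when adjusted over the list alone. The matrix protease Mmp9 rose from 4.05 ± 0.45 to 22.4 ± 1.22 FPKM (log2 fold change 2.22, SE 0.13, adjusted p = 0.000526), and the monocyte chemokine Ccl2 from 206 ± 26.9 to 684 ± 33.7 FPKM (1.73, SE 0.15). Cxcl1, a neutrophil chemokine, rose from 18.8 to 179 FPKM. The list had a median of 1.13 (0.74 without any filter) and passed camera (adjusted p = 4.29e-05, adjusted p = 0.386 with an estimated correlation). Risen members numbered 4, 8 and 13 without control 1, 2 or 3 and 3, 3 and 4 without irradiated library 1, 2 or 3.

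Among surface signals to phagocytes and T cells, 5 of 12 genes tested rose, and 6 when adjusted over the list alone. Lgals9, which encodes galectin-9, rose from 40.2 ± 4.70 to 132 ± 24.9 FPKM (log2 fold change 1.68, SE 0.18, adjusted p = 0.00398). Raet1e, a ligand of the NKG2D receptor, rose from 2.40 to 11.2 FPKM and Cd274, which encodes PD-L1, from 0.323 to 1.92 FPKM. Cd47, the "don't eat me" signal (NCBI gene 16423, chromosome 16, 49851328 to 49912503), had a log2 fold change of 0.51 (SE 0.11, adjusted p = 0.0343), and every irradiated library lay above every control. The Cd47 call was lost after scaling by a trimmed mean of log ratios (0.31, adjusted p = 0.124) and on leaving out control 1 or 2 or any irradiated library (adjusted p = 0.134, 0.0592, 0.205, 0.201 and 0.168), within a range of adjusted p up to 0.205 over all alternatives. Calr, the opposing "eat me" signal, measured 880 ± 136 FPKM in controls and 872 ± 4.93 in irradiated cells and did not pass (adjusted p = 0.995). Leaving out irradiated library 1 ended the calls of Lgals9 (adjusted p = 0.0535) and Raet1e (0.0531), irradiated library 2 or 3 that of Raet1e (0.0719 and 0.0675), with Cd274 below the filter and not tested in these 3 settings, and control 1 those of Raet1e (0.0504) and Cd274 (0.0591). The list had a median of 0.50 (0.17 without any filter and 0.31 after trimmed-mean scaling) and a camera adjusted p of 0.00969 (adjusted p = 0.471 with an estimated correlation), and lost its call without control 3 (adjusted p = 0.0626). Its risen members were 1, 4 and 8 without control 1, 2 or 3 and 0, 1 and 1 without irradiated library 1, 2 or 3.

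Genes induced by p53 rose in 10 of 27 tested, and in 16 when adjusted over the list alone, and none of the 27 fell. Mdm2, the ubiquitin ligase of p53 (NCBI gene 17246, chromosome 10, 117688875 to 117710758), rose from 82.8 ± 2.69 to 279 ± 13.4 FPKM (log2 fold change 1.74, SE 0.12, adjusted p = 0.000838). Cdkn1a, the cell cycle inhibitor p21, rose from 113 ± 13.6 to 211 ± 6.43 FPKM (0.90, SE 0.14, adjusted p = 0.0145). Fas, a death receptor, rose from 0.287 to 2.90 FPKM and the antiproliferative gene Btg2 from 0.96 to 4.72 FPKM. Trp53 itself did not pass (0.19, SE 0.15, adjusted p = 0.344; 0.09 without control 2, -0.01 after trimmed-mean scaling and 0.42 after quantile normalization). The list median was 0.80 (camera adjusted p = 6.66e-05, adjusted p = 0.471 with an estimated correlation), and was lower after quantile normalization (0.47) and against control 3 alone (0.40). The risen members were 3, 5 and 22 (with 2 that fell) without control 1, 2 or 3 and 2 without each irradiated library, and the Cdkn1a call was lost after scaling by a trimmed mean of log ratios (adjusted p = 0.0565) and without control 1 (0.0665) or irradiated library 1, 2 or 3 (0.139, 0.154 and 0.119).

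Few cell cycle genes passed the test. No member of the 28 mitosis genes passed limma over all genes or adjusted over the list alone, and 5 had an unadjusted p below 0.05. Cdc25c and Cdk1, which drive entry into mitosis, had log2 fold changes of -0.85 (adjusted p = 0.0656) and -0.77 (adjusted p = 0.0954). Of 28 DNA replication genes, Tk1, the thymidine kinase of S phase, fell from 145 ± 47.4 to 63.5 ± 2.90 FPKM (log2 fold change -1.11, SE 0.26, adjusted p = 0.0437), and none passed when adjusted over the list alone. Gins1 had a log2 fold change of -0.74 (adjusted p = 0.0642). Without control 3, Cdc25c, Cdk1 and Gins1 were called lower (limma adjusted p = 0.000212, 6.25e-05 and 0.00011). In that setting 7638 of all 11053 genes tested were called, and 5 mitosis genes rose and 8 fell, as did 5 and 11 replication genes. The Tk1 call was lost without any filter (adjusted p = 0.06), with the stricter filter (0.0517) and without control 1 (0.163), control 2 (0.0934) or irradiated library 1, 2 or 3 (0.2, 0.207 and 0.169). Both lists passed camera downward relative to other genes, at medians of -0.13 and -0.07 (adjusted p = 0.0151 and 0.0262; adjusted p = 0.659 and 0.717 with an estimated correlation), and both lost the call after quantile normalization (adjusted p = 0.606 and 0.315), with the filter at 5 FPKM (0.0552 and 0.0865) and without irradiated library 2 (0.0989 and 0.111). The replication list also lost it without control 1 (0.106) and against control 3 alone (0.516), where its median was 0.00. Trimmed-mean scaling gave medians of -0.33 and -0.27, quantile normalization -0.05 and -0.08, and the length and GC correction -0.17 and -0.21. The mitosis median was -0.07 without control 1, and that of replication was -0.01, -0.15 and -0.13 without control 1, 2 or 3 and -0.03 and -0.12 without irradiated library 2 or 3. Among repair genes, 0 of 20 homologous recombination genes were called by limma, with 4 at an unadjusted p below 0.05. Of 13 end joining genes, Lig4, the ligase of the pathway, and Dclre1c, the nuclease Artemis, rose by 1.01 and 1.46, and the same number passed when adjusted over the list alone. Neither repair list passed camera (adjusted p = 0.527 and 0.921). Without control 3, 8 recombination genes rose and 1 fell, as did 6 and 4 end joining genes. Without control 1 or any irradiated library, 0 genes of either list were called, and without control 2, 1 end joining gene.

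Enzymes of cholesterol synthesis fell in 11 of 19 genes tested, and in 15 when adjusted over the list alone, and none rose. Fdps, farnesyl diphosphate synthase (NCBI gene 110196, chromosome 3, 89093588 to 89101967), fell from 591 ± 127 to 141 ± 9.75 FPKM (log2 fold change -2.04, SE 0.19, adjusted p = 0.00288). Fdft1, which makes squalene, fell from 130 ± 16.5 to 37.6 ± 2.99 FPKM (-1.76, SE 0.14, adjusted p = 0.00179) and Msmo1 from 241 ± 21.6 to 79.3 ± 4.41 FPKM (-1.59, SE 0.13). Mvd and Pmvk, enzymes of the mevalonate pathway, fell by 1.87 and 2.13 on the log2 scale. Both calls were lost without control 1 (adjusted p = 0.0603 and 0.0704) and without irradiated library 1 (0.0735 and 0.0845), 2 (0.0619 and 0.089) or 3 (0.0712 and 0.0861). The list median was -1.06 (camera adjusted p = 3.96e-14, adjusted p = 0.386 with an estimated correlation), and it was -1.04, -0.79 and -1.21 when the irradiated mean was set against control 1, 2 or 3 alone. Fallen members numbered 5, 15 and 16 without control 1, 2 or 3 and 4 without each irradiated library.

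**Figure D3:**
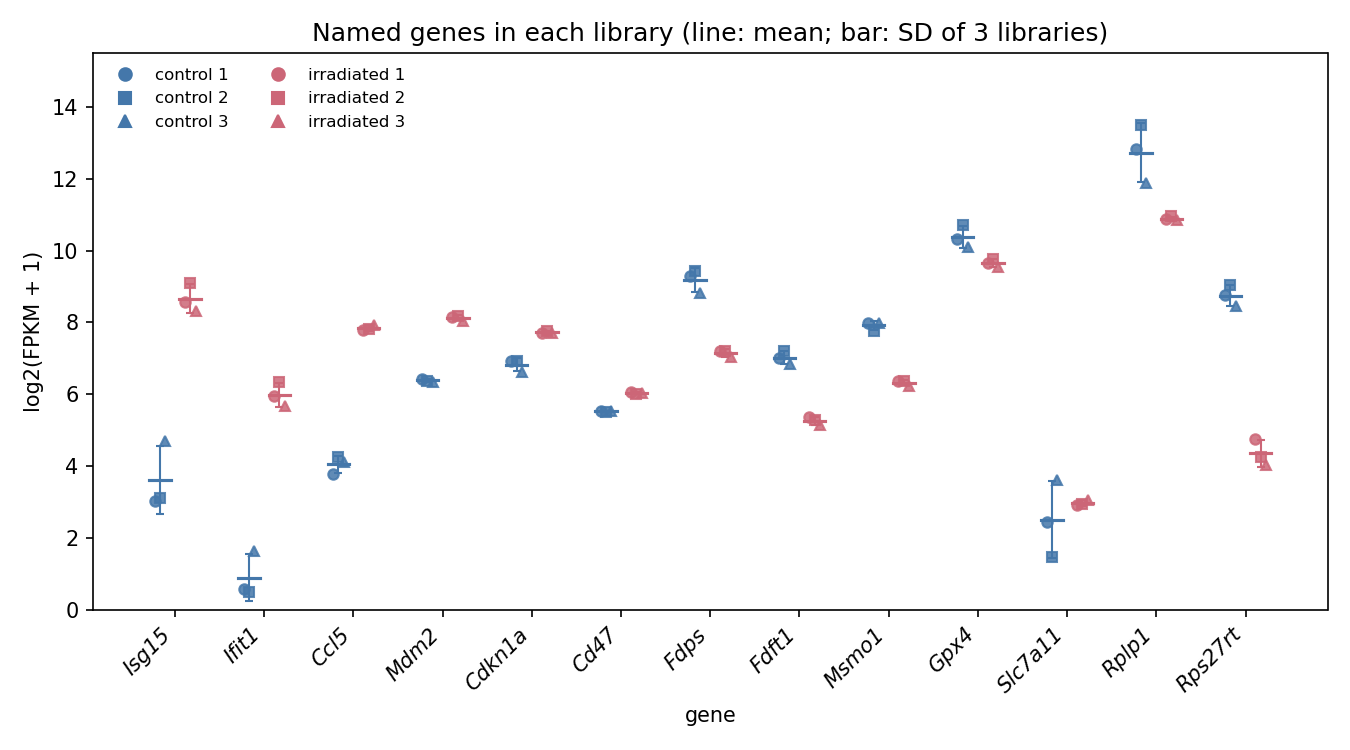
Points are log2(FPKM + 1) of named genes in each of the 6 libraries, with the mean as a line and the SD of 3 libraries as a bar. Mdm2, Ccl5, Fdft1 and Msmo1 differ between groups by far more than the spread of either group, whereas the controls of Slc7a11 span the irradiated values.

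Genes that protect from ferroptosis, a form of cell death by lipid peroxidation, did not pass camera as a group. Of 22 tested, Aifm2, which encodes FSP1, rose and Scd2, a fatty acid desaturase, fell, and 1 rose and 3 fell when adjusted over the list alone. Scd2 fell from 172 ± 20.9 to 76.3 ± 1.19 FPKM (log2 fold change -1.16, SE 0.14, adjusted p = 0.00522), and this call was lost without irradiated library 1, 2 or 3 (adjusted p = 0.0749, 0.08 and 0.0715). Aifm2 went from 16.3 ± 1.06 to 23.8 ± 1.39 FPKM (0.52, adjusted p = 0.0411). Gpx4, the glutathione peroxidase that reduces lipid peroxides (NCBI gene 625249, chromosome 10, 80047166 to 80056439), measured 1351 ± 298 FPKM in controls and 807 ± 59.7 in irradiated cells, a difference that just missed the threshold (-0.72, SE 0.20, adjusted p = 0.0574). Gpx4 was called lower without control 3 (-0.86, adjusted p = 0.00069) by limma without trend and robust options (0.0469) and against control 3 alone (-0.44, adjusted p = 0.00754), but its log2 fold change was -0.37 after the length and GC correction (0.0691) and -0.23 after quantile normalization (0.191). Slc7a11, the cystine transporter, measured 4.43, 1.77 and 11.4 FPKM in controls 1 to 3 and 6.85 ± 0.426 in irradiated cells (0.46, adjusted p = 0.503). Slc7a11 measured -0.06 without control 2 and was called higher without control 3 (1.02, adjusted p = 0.00598) and lower against control 3 alone (-0.66, adjusted p = 0.00231). Without control 3, 9 members of the list rose and 6 fell, in a setting that called 7638 of all 11053 genes tested. These counts therefore say little about the list itself. Without any 1 irradiated library none was called.

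Of 20 genes that promote or mark ferroptosis, 3 rose, and 4 rose and 1 fell when adjusted over the list alone. Hmox1, heme oxygenase 1, rose from 83.8 ± 21.8 to 195 ± 9.29 FPKM (log2 fold change 1.24, SE 0.21, adjusted p = 0.0185), the ferrireductase Steap3 by 0.74 and the iron transporter Slc11a2 by 0.63. Acsl4, which supplies polyunsaturated lipids, did not pass (-0.24, adjusted p = 0.451), though it was called lower after the length and GC correction (-0.66, adjusted p = 0.0135) and against control 3 alone (-0.74, adjusted p = 0.000631). Its log2 fold change was -0.42 without control 2, -0.43 after trimmed-mean scaling and 0.01 without control 3, so the difference rested on that library. The calls of Aifm2 and Slc11a2 were lost after quantile normalization (adjusted p = 0.072 and 0.0878) and trimmed-mean scaling (0.102 and 0.118). Those of Aifm2, Hmox1, Steap3 and Slc11a2 were lost without control 1 (adjusted p = 0.157, 0.0943, 0.112 and 0.123) and without any irradiated library (0.12 to 0.21), and those of Aifm2 and Slc11a2 without control 2 (0.0737 and 0.0618). Neither ferroptosis list passed camera (adjusted p = 0.282 and 0.798), which pointed down relative to other genes although the medians were 0.13 and 0.16; after trimmed-mean scaling the medians were -0.07 and -0.04, and after quantile normalization -0.05 and 0.08. The defence median was 0.02 and -0.06 without control 2 or 3 and 0.08 without any filter or with the filter at 5 FPKM, and that of the promoting genes was 0.02 and -0.06 without control 1 or 2, 0.06 without any filter, 0.01 with the filter at 5 FPKM and 0.32 after the length and GC correction. Without control 3, 8 of the promoting genes rose and 3 fell, where 7638 of all 11053 genes tested were called.

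Glutamine transport and metabolism genes showed 1 rise among 23 tested, and 1 when adjusted over the list alone. That gene was Glul, glutamine synthetase, which rose from 27.9 ± 3.48 to 51.5 ± 3.03 FPKM (log2 fold change 0.87, SE 0.14, adjusted p = 0.0148). The call of Glul was lost without control 1 (adjusted p = 0.0599) or irradiated library 1, 2 or 3 (0.119, 0.147 and 0.126). Gls2, Slc3a2 and the glutamine transporter Slc1a5 had log2 fold changes of 0.54, -0.53 and -0.58 and did not pass (adjusted p = 0.106, 0.119 and 0.122); without control 3, Slc3a2 and Slc1a5 were called lower at smaller falls (-0.32 each, adjusted p = 0.0421 and 0.0368). Against control 3 alone Gls2 was called higher (0.72, adjusted p = 0.0432) and Slc3a2 and Slc1a5 lower (-0.94 and -1.09, adjusted p = 0.000125 and 0.000101). Gls2 was also called after the length and GC correction (0.88, adjusted p = 0.04) but measured 0.07 after quantile normalization (0.829). Over the list, 11 members rose and 2 fell without control 3, where 7638 of all 11053 genes tested were called. The list median was 0.10 with camera pointing down (adjusted p = 0.594), and against controls 1, 2 and 3 taken singly it was 0.19, 0.38 and -0.17, and after trimmed-mean scaling -0.10. It was 0.03, -0.15 and 0.33 without control 1, 2 or 3, 0.03 without irradiated library 2 and 0.00 after quantile normalization or with the filter at 5 FPKM. Against control 3 alone the list passed camera downward (adjusted p = 0.000367).

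ATF4 target genes, which include several amino acid synthesis and transport genes, were higher in control 3 than in the other controls, and no member of 18 was called over all genes or adjusted over the list alone, with 3 at an unadjusted p below 0.05 (median -0.07, camera adjusted p = 0.158). The median was -0.27 after trimmed-mean scaling, 0.13 with the filter at 5 FPKM and 0.79 without control 3. The list passed camera downward without control 1 or 2 (medians -0.32 and -0.46, adjusted p = 0.0124 and 0.0109). Without control 3, 10 members were called higher and 3 lower, where 7638 of all 11053 genes tested were called. Against control 3 alone, 0 rose and 16 of 18 fell, with a median of -1.45 (camera adjusted p = 2.21e-16). Trib3, for example, measured 10.7, 10.7 and 107 FPKM in controls 1 to 3 and 15.4 to 18.9 FPKM in the irradiated libraries.

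Cytosolic ribosomal protein genes fell in 17 of 81 tested, and in 54 when adjusted over the list alone, and none rose. Rplp1, a protein of the ribosomal stalk, fell from 7499 ± 3857 to 1899 ± 71.3 FPKM (log2 fold change -1.84, SE 0.39, adjusted p = 0.0358). Rpl22l1 fell by 1.43 and Rpl39 by 0.95 on the log2 scale. The list median was -0.72 (camera adjusted p = 1.64e-24, adjusted p = 0.547 with an estimated correlation), and against controls 1, 2 and 3 taken singly it was -0.84, -1.09 and -0.26; after quantile normalization it was -0.23. Fallen members were 0, 5 and 79 without control 1, 2 or 3 and 0 without each irradiated library, and the call of Rpl39 was lost after quantile normalization (adjusted p = 0.0575). Rplp1, Rpl22l1 and Rpl39 lost their calls without control 1 (adjusted p = 0.149, 0.061 and 0.0836) or any irradiated library (0.0709 to 0.191), and Rplp1 also without control 2 (0.0534). Across genes, which are not independent replicates, shorter and GC-richer transcripts were higher in controls 1 and 2 than in control 3 (Spearman rho of the difference between controls 1 and 3 was -0.384 with length and 0.323 with GC content). The main log2 fold change, irradiated minus control, carried this trend too (rho 0.358 with length and -0.245 with GC content). Between control 3 and the irradiated libraries the trend with length was weaker (rho -0.123 to -0.076). For controls 1 and 2 it was -0.397 to -0.353, so comparisons without control 3 carry that trend. Rps27rt (NCBI gene 100043813, chromosome 9, 114982366 to 114982739) and Rpl37rt, retrocopies of Rps27 and Rpl37, had the largest falls under the rule for named genes, at -4.40 and -3.67 (adjusted p = 0.000526 and 0.000836). Reads of a retrocopy can be assigned to its parent gene, so these values are uncertain. Crabp1, which binds retinoic acid, and Cyp3a41a, a cytochrome P450 of a family with close paralogs, fell by 2.20 and 2.47. The Crabp1 call was lost without control 1 (adjusted p = 0.0685) or irradiated library 1, 2 or 3 (0.099, 0.0867 and 0.0861).

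The remaining lists did not pass camera in the comparison of all 6 libraries. NRF2 target genes had 3 rises and 2 falls among 20 tested, led by a rise of Gsta4, a glutathione transferase, from 21.9 to 55.8 FPKM (adjusted over the list alone, 4 and 3; camera adjusted p = 0.722). Immediate early genes had 2 rises among 16, Btg2 and Junb (5 rises and 1 fall adjusted over the list alone; adjusted p = 0.158). Of 15 unfolded protein response genes, the chaperone Dnajc3 fell (none adjusted over the list alone; adjusted p = 0.138), and of 20 glycolysis and hypoxia genes Egln3 rose and Pfkl fell (1 and 1 adjusted over the list alone; adjusted p = 0.339, pointing down with a median of 0.12, which was -0.02 without control 2 and 0.07 without irradiated library 2). Bcl2l11 and Bid, which promote apoptosis, rose by 1.15 and 1.30 among 12 BCL2 family genes (2 adjusted over the list alone; adjusted p = 0.434). Replication-dependent histone genes had 6 rises and 1 fall among 43 (10 and 2 adjusted over the list alone; adjusted p = 0.109), and histone genes have close paralogs. The histone list passed camera upward after trimmed-mean scaling (adjusted p = 0.0262), after the length and GC correction (0.000819), against control 3 alone (0.0209), and without control 2 (0.0368) or irradiated library 1 (0.0484), and the glycolysis list passed downward against control 3 alone (0.0452). The NRF2 list passed upward after quantile normalization (0.0119) and the unfolded protein response list downward without control 2 (0.0257).

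Only 5 of the 23 epithelial genes in the table passed the filter, and the 23 had a median of 0.04 to 0.19 FPKM per library. Krt5, Krt14, Cdh1 and Epcam measured at most 0.49 FPKM in any library, and Trp63 at most 1.1 FPKM, in control 3. Not all of the 23 were low: the highest member reached 487 to 1361 FPKM in the controls and 371 to 393 FPKM in the irradiated libraries. Of the 5 epithelial genes tested, Sprr1a, a cornified envelope protein, rose from 23.5 to 296 FPKM, Sprr1b and Krt16 rose and Krt18 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.434). Among 15 mesenchymal genes, 2 rose, among them the collagen gene Col1a1, and Tgfbi fell (4 and 3 adjusted over the list alone; adjusted p = 0.828, pointing down with a median of 0.32, which was 0.20, 0.07 and 0.49 without control 1, 2 or 3). Fibroblast markers had 3 rises among 7, Mfap5, Col1a1 and Dcn (3 adjusted over the list alone; adjusted p = 0.315). Leukocyte and endothelial markers were near the floor: 2 leukocyte markers were tested, of which Lyz2 rose from 0.533 to 3.09 FPKM (1 adjusted over the list alone), and 0 of 7 endothelial markers reached the filter. Over the 9 lists of this and the preceding paragraph that had a camera test, 22 rises and 7 falls became 10 and 0, 20 and 2, and 71 and 28 without control 1, 2 or 3, and 2, 3 and 7 rises with 0 falls without irradiated library 1, 2 or 3. Genes of the mitochondrial genome were not analysed here.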

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

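The length and GC correction and the comparison with control 3 as the only control were chosen after seeing the data. In none of the 15 alternatives was a called gene called in the opposite direction. Of 41 called named genes, 16 were called in all 15 alternatives, where a gene below the filter counts as not called, and of all 1334 called genes, 53 were (43 higher, 10 lower, 15 of them on the interferon list). The number of calls was within 1.5 times of 1334 under quantile normalization, trimmed-mean scaling, no filter, limma without trend and robust options, a pseudocount of 0.1, and the length and GC correction (1050 to 1691). It was 727 with a filter at 5 FPKM, where fewer genes were tested, and 4093 with control 3 as the only control. In that last setting the lone control is assumed to vary like the irradiated libraries, which the median SD of 0.30 among controls and 0.08 among irradiated libraries contradicts, so its calls serve as a description. At 2-fold, 545 genes became 329 with the filter at 5 FPKM. Leaving out one replicate gave 56 to 7638 calls, 56 to 1990 at 2-fold and 7 to 12 lists. The count of 9 lists became 0 of 24 with an estimated correlation (camera of limma; 3 lists had an unadjusted p below 0.05, and the smallest adjusted p was 0.386). With control 3 as the only control, Slc7a11, which was not called, changed sign and was called (-0.66, adjusted p = 0.00231); it was higher in control 3 than in controls 1 and 2. With the sample number as a replicate block, 300 genes were called (298 shared with the main result) and 291 at 2-fold, and the histone list passed camera upward (adjusted p = 0.0407). Of the named genes, 11 lost their call with this block, among them Cd47, Cdkn1a, Hmox1 and Glul (limma adjusted p = 0.105, 0.0659, 0.055 and 0.0641). Samples with equal numbers showed no sign of deviating together (correlations -0.115, 0.02 and -0.159), but 3 such correlations cannot exclude that the numbers pair the samples. Where the setting itself gives no reason, the cause was not tested. A count test on recovered reads was not run, because the rounded values did not resolve into whole reads. The unknown depth limits what can be said of genes with low FPKM.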

Other observations

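The test of a mislabelled control 3, the tests against the nearest control, the spread between libraries used to judge the list medians, the leukocyte test and the test of near-identical copies were chosen only after the results were seen; the comparison with control 3 alone was added then too. The test of control 3 was revised after earlier versions of it had been seen, and the comparison with genes that rose was added to the test of copies, and the 2 retrocopies that prompted it left out, after its first exact p was known.

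Beyond the fixed lists, several genes of the interferon response and of innate defence were among the largest rises; these were picked after their values were seen. Lcn2, an iron-binding protein of innate immunity, rose from 0.203 to 32.7 FPKM (log2 fold change 4.80, limma adjusted p = 0.000222), and complement C3 from 0.893 to 35.4 FPKM. The interferon-induced GTPases Igtp, Irgm2 and Gbp3 rose by 4.39, 4.27 and 4.98. Of genes that encode sensors of nucleic acids or their adaptors, Tlr3 rose by 1.53 (adjusted p = 0.00739), as did Ifih1 and Ddx58 of the fixed interferon list by 3.55 and 2.68 (adjusted p = 0.00179 and 0.00452), while Cgas (0.30, adjusted p = 0.182) and Mavs (0.55, adjusted p = 0.17) did not pass and Sting1 just missed the threshold (0.51, unadjusted p = 0.00604). Ifnb1, which encodes interferon beta, was listed at 0 in all 3 controls and at 0.51, 0.26 and 0 FPKM in the irradiated libraries. Rnaseh2a, a subunit of the enzyme that removes RNA from DNA hybrids, fell from 69.9 ± 13.4 to 37.1 ± 1.71 FPKM (limma adjusted p = 0.0254), while Adar, which edits double-stranded RNA, rose from 10.8 ± 3.38 to 31.9 ± 5.10 FPKM (adjusted p = 0.0139). Ciita, the master regulator of MHC class II, stayed at or below 0.11 FPKM in all 6 libraries.

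Interferon-stimulated genes were higher in irradiated cells with a median log2 fold change of 3.79. After each library's trend with length and GC content was removed the median was 4.07 (95% Welch interval between libraries 3.51 to 4.63), and against the nearest control, control 3, it was 3.48 with or without that correction, while the control libraries spanned 0.48 and 0.36, which argues against the trend, a difference among controls and both together as the whole cause. RNA of leukocytes would bring abundant leukocyte transcripts, but the median leukocyte marker reached at most 0.222% of the list's median FPKM in any irradiated library, with Lyz2 at a mean of 3.09 FPKM and Ptprc at most 0.03. The markers cover several lineages, so their median could stay low if a single lineage were present. The highest marker reached 5.48, 5.63 and 4.01 FPKM in irradiated libraries 1 to 3, where the interferon list had medians of 39.7, 49.6 and 28.2 FPKM. In controls 1 to 3 the highest marker reached 4.52, 3.59 and 2.11 FPKM. A response of the tumour cells to radiotherapy is a hypothesis that may account for the rise and that the design names. The labels give no batch, so none was tested.

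ATF4 target genes were highest in control 3, where their median lay 1.72 above the higher of controls 1 and 2 on the log2 scale; Chac1 measured 10.3, 9.08 and 141 FPKM and Asns 48.8, 40.8 and 236 FPKM in controls 1 to 3. Removing the length and GC trend left a median of 1.98, while the list medians of the other 5 libraries spanned 0.86, which argues against that trend as the whole cause. An irradiated library carrying the label of control 3 is argued against by the fixed interferon list, whose median in control 3 lay 3.44 below that of the lowest irradiated library, while libraries within a group spanned at most 0.45; for p53 targets the gap was 0.45, where the controls spanned 0.48. No biological explanation given by the design was tested, because the labels treat the 3 controls alike.

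Ribosomal protein genes were lower in irradiated cells with a median of -0.72, which became -0.52 after the length and GC correction (95% Welch interval between libraries -1.11 to 0.08), -0.26 against the nearest control, where controls spanned 0.82, and -0.25 with both, where they spanned 0.47, so the trend, a difference among controls and both together stay open as the whole cause. A bootstrap over the members, set as the first test of the correction, had left 0 outside (-0.61 to -0.48), but these genes move together within a library (estimated correlation 0.831), so it does not measure the spread between libraries. The retrocopy Rps27rt, identical to Rps27 over the matched part, took 7.05%, 6.86% and 7.75% of the summed FPKM of Rps27 and Rps27rt in controls and 0.84%, 0.59% and 0.54% in irradiated libraries, and Rpl37rt, for which the search found no near-identical copy, took 11.1% to 12.1% of its pair with Rpl37 against 0.96% to 1.16%. If reads shared between copies were assigned differently in the groups, genes with a near-identical copy should be frequent among large falls. Such reads can raise the other copy, so large rises could carry copies too. Without these 2 retrocopies, 2 of 9 genes with a sequence called at least 4-fold lower had such a copy (22.2%, exact binomial 95% interval 2.8 to 60%). They include Gm6109, near-identical to Rpl30. The share was 1.99% of the other genes (two-sided Fisher's exact p = 0.0131) and 12.2% of those called at least 4-fold higher (p = 0.336). Genes called at least 4-fold higher also carried a copy more often than the remaining genes (Fisher's exact p = 1.69e-06). The comparison of falls with rises therefore cannot decide, and that explanation stays open. The shares of the 2 retrocopies in their pairs separated all controls, control 3 included, from all irradiated libraries. A difference in read assignment between the groups would give this too, and the design cannot tell it apart from radiotherapy. A response of the cells to radiotherapy stays open too.

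There were 13 genes listed at 0 in all 3 controls and at 1 FPKM or more in every irradiated library, and 0 the other way round. Of the 10 with a transcript sequence, 7 had a near-identical copy, while Ccl4, Gbp10 and Nos2 had none. The 7 were Asdurf (near-identical to Asnsd1), Defa22, Defa24, Defa33, Defa43, Gm4302 and H2ac19. The search ignored position, so gene entries that overlap at the same locus would also count as copies. Genes at 0 numbered 2901 to 2944 in the controls and 1713 to 1899 in the irradiated libraries. Whether both groups were counted with the same settings and annotation is not given in the sources used here, so these zeros, and large changes of genes with copies, are uncertain.

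With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1334 calls and 545 at 2-fold, and 1 of the 10 splits, the real one, gave as many. The highest other split gave 0 for both by limma (5 to 1411 genes at an unadjusted p below 0.05, against 4251). Every other split mixes irradiated and control libraries within its groups. A difference between irradiated and control cells then adds to the spread, so these 0 calls do not show what chance alone would give. For the fixed lists the real split called 9 and the highest other 12, and 5 of the 10 splits called as many. The camera p of the real split was the smallest of the 10 for the interferon, p53, inflammatory, innate checkpoint and ribosomal protein lists, whereas 3 of the 10 splits, the real one included, gave a p as small for cholesterol synthesis and for MHC class I, 4 for mitosis and 5 for DNA replication, and for ATF4 targets all 10 did.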
